A study of Homo sapiens with 4 samples.

How the data were processed

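The series holds 4 libraries from CaSki cells, an established line of cervical squamous carcinoma cells that carries integrated human papillomavirus. The cells were cultured at 37 °C, and the treated cells were kept at 42 °C for 60 min before the assay, per the labels. For each of the 2 conditions there was 1 library of RNA immunoprecipitated with a commercial kit for N6-methyladenosine (m6A, the most common internal modification of mRNA) and 1 input library of RNA that was not immunoprecipitated. Total RNA was extracted with a phenol-based reagent, per the labels' protocols. This assay, MeRIP-seq, reports regions where RNA fragments bound by the antibody pile up above the input. It does not resolve single bases.

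The deposited files are 1 peak list per condition, with a position, a length, a gene, a transcript and the peak caller's values for each peak. Reads were trimmed with cutadapt 1.9.3 and aligned with STAR to hg19, per the submitters' processing notes; the version of STAR is not given in the sources used here. The peak names in the files begin with MACS, and the caller's version and settings are not given in the sources used here. The files are titled as sites in mRNA. The peak numbers run to 58312 in the control list and to 64647 in the heat list, so the listed peaks make up 24.6% and 23.9% of the numbers, and the remaining numbered peaks were not analysed here. Within each list no regions overlapped. The end minus the start equals the stated length in the files, as in BED format, so that 1 was added to each start and coordinates are given 1-based.

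The deposited significance is a score, minus 10 times the log10 of the caller's p-value per the file headers, with a lowest listed value of 50, which is 1e-05 before the conversion. It levels off at 3100, a value that 1466 control peaks and 752 heat peaks reached or passed. The many peaks with exactly that score were ordered by fold. Peaks with a higher score, up to 3233 in control and 3228 in heat, were placed before them. Whether exactly 3100 marks a lower or a higher significance than these scores is not given in the sources used here. The order of these peaks is therefore uncertain. The deposited fold enrichment is a ratio of immunoprecipitated signal to the background that the caller estimated, per the file headers, and the scaling between libraries is not given. The deposited false discovery rate is in percent, per the file headers. All of these are the authors' values for single peaks of 1 library against its input. They were used to describe, rank and filter peaks within a list, and were not compared between lists as a change. Total reads per library are not in the analysed values, so the depth behind each peak is unknown.

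With 1 immunoprecipitated library per condition there is no replicate, so no p-value was computed for any difference between conditions. Peaks were called shared when regions of the lists overlapped by at least 1 base (bedtools 2.31.1), without regard to strand, which the files do not give. A peak absent from a list can lie under the caller's threshold or among the numbered peaks that are not listed. Shares carry 95% Wilson intervals, and shares of single-list genes exact binomial intervals. Both cover the counting of peaks or genes only, and neither covers the spread between cultures, since genes are not replicates.

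A gene was placed in both lists, in control only or in heat only by its symbol in the files. Of 8220 symbols, 8048 had a gene identifier, 8037 of these were found in the RefSeq gene table of GRCh38.p14, and 415 have since been renamed; the files' symbols are printed. No coordinate was taken from that table. For 13 named gene lists and 2 classes of symbols (ZNF zinc finger genes and RPL or RPS ribosomal protein genes) the heat-only minus control-only share was placed among 10000 random lists of the same size, drawn from genes with a peak in either list and matched on quintile of the number of peaks. This percentile describes these libraries and is not a test across replicates. Scripts were tested on simulated data: all 7000 planted shared regions were found. Of 100 random lists of 20 genes, 2 fell outside the 2.5th to 97.5th percentile, and 93 of 100 lists with 8 planted heat-only genes lay above it.

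The lists, the main comparisons and the rule for naming genes were fixed before the data were examined; peak numbers per gene, free peak numbers, chromosomes and ontology terms were looked at afterwards. The text names the 10 genes of each single-list class with the most significant peak, ties ordered by fold, and the 5 genes in both lists with the lowest sum of ranks. It also names up to 4 single-list members and 2 shared members of each gene list, and any heat shock gene; symbols that are only an identifier were passed over, and a few genes that the rule takes are not reported here. The alternatives were a fold above 36.5, the median of both lists pooled, which keeps more of the control list because its folds run higher, a significance above 203, equal numbers of top peaks from each list (14367 or 7183), merging of regions within 100 bases, a 50% reciprocal overlap, midpoints within 100 bases, stricter peaks of 1 list against all of the other, and random lists without matching. The planned comparisons of peak position along transcripts and of the DRACH motif were not made, because no hg19 sequence or transcript models were used here. In the heat list 1 line had been emptied for this work and was not analysed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.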

Results

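The transcriptome-wide distribution of m6A was mapped in CaSki cervical carcinoma cells kept at 37 °C or exposed to 42 °C for 60 min, with 1 immunoprecipitated and 1 input library per condition. The question was how heat stress alters m6A. The authors' lists held 14367 peaks in 7138 genes for control cells and 15472 peaks in 7112 genes for heated cells. About the same share of genes carried a single peak, 52.7% (3760 genes) in control and 50.6% (3597 genes) in heat. The peaks had a median length of 537 bases in the control list and 417 bases in the heat list, and covered 12 and 11.5 megabases. The median fold enrichment over background was 43.3 within the control list (lower and upper quartile 27.8 and 79.1) and 31.6 within the heat list (21.3 and 51.1). The caller's own false discovery rate was high: it was 100% for 6962 control peaks (48.5%) and for 8230 heat peaks (53.2%), and the lowest listed value was 8.22% in control and 20.6% in heat. No difference below has a replicate check, since each condition had 1 immunoprecipitated library.

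Most peaks at the authors' threshold were found in both conditions. Of the control peaks, 10305 overlapped a heat peak (71.7%, 95% Wilson interval 71.0 to 72.5%), and of the heat peaks 10313 overlapped a control peak (66.7%, 65.9 to 67.4%). Above a fold of 36.5 in both lists, which 8488 control peaks and 6405 heat peaks passed, 47.6% of the control peaks overlapped a heat peak. In 6780 cases the region had the same start and the same end in both lists. Whether boundaries follow exon limits rather than reads was not checked, so identical boundaries and peak lengths do not show identical m6A sites. The shared genes with the lowest sum of significance ranks over both lists included CLPB, a mitochondrial disaggregase, ACTN1, an actin crosslinker, ARHGAP22, a GTPase-activating protein for Rac, and ING1, a chromatin reader of the ING family. CLPB had 8 peaks in each list. Its highest-scored peak lay at chromosome 11, positions 72003470 to 72004659 (hg19). The fold enrichment there was 71.4 in the control list and 129 in the heat list. ACTN1 had 7 control and 9 heat peaks.

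Peaks present in 1 list only numbered 4062 in control (28.3%, 27.5 to 29.0%) and 5159 in heat (33.3%, 32.6 to 34.1%). They were weaker and shorter than the shared peaks of the same list. The median fold enrichment of single-list peaks was 34.7 against 50.1 for shared peaks in the control list, and 25.5 against 36.7 in the heat list, and the median length was 334.5 against 645 bases and 206 against 633 bases. The share of single-list peaks fell from 60.4% (57.9 to 62.9%) in the least significant decile of the control list to 1.67% (1.12 to 2.47%) in the most significant decile, and in the heat list from 66.0% (63.6 to 68.3%) to 3.55% (2.74 to 4.60%). Most single-list peaks lay in genes that also had a peak in the other list: 2775 of the control peaks (68.3%) and 3709 of the heat peaks (71.9%). Numbered peaks that the lists leave out limit what absence means. Of the single-list peaks with a listed peak on both sides in the other list, 4042 in control and 5146 in heat, only 133 and 181 lay between peaks with consecutive numbers, which leaves no room for an unlisted peak. A free number does not show that an unlisted peak lay at the site. Most numbers are unlisted, the median of these gaps held 6 of them, and gaps elsewhere were not compared.

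**Figure D1:**
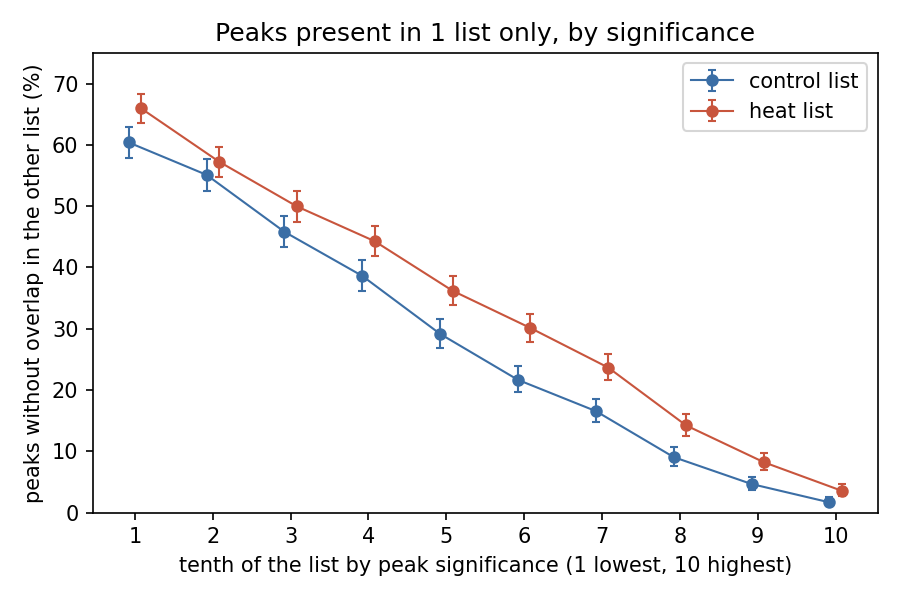
Percentage of peaks without an overlapping peak in the other list (y axis) in each decile of the control list (blue) and the heat list (red), ordered by the caller's significance (x axis); bars are 95% Wilson intervals for the counting of peaks. The share falls from 60.4% to 1.67% in the control list and from 66.0% to 3.55% in the heat list.

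At the level of genes, 6030 of the 8220 genes with any peak had peaks in both conditions (73.4%, 95% Wilson interval 72.4 to 74.3%), 1108 in control only (13.5%, 12.8 to 14.2%) and 1082 in heat only (13.2%, 12.4 to 13.9%). The single-list genes divided evenly, with 49.4% (exact interval 47.3 to 51.5%) in heat only. Only 8 control-only and 9 heat-only genes had a peak that overlapped a peak assigned to another gene in the other list. Of the control-only genes 947 (85.5%) had a single peak, and of the heat-only genes 836 (77.3%). With a significance score above 203 required in 1 list and no peak at all in the other, 370 genes were control only and 321 heat only. The even division did not hold under the other thresholds tried, all of which gave more control-only genes. The heat-only share was 43.1% (41.0 to 45.2%) with 14367 top peaks from each list and 41.3% with 7183, 37.5% with a significance score above 203, 39.5% with a listed false discovery rate under 100%, and 28.8% above a fold of 36.5. Part of this direction follows from the settings. Taking 14367 top peaks shortens only the heat list. The limits on score, fold and listed false discovery rate kept more control than heat peaks. Only the 7183 top peaks cut both lists to the same length.

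The control-only genes with the strongest peaks were FAM46B, FURIN, PDF, DDX19A, ZNF581, ESRP2, POLE3, B3GALT6, SAMD9 and CEBPB, all at the ceiling of the significance score. FURIN, the proprotein convertase, had 1 control peak of 245-fold enrichment at chromosome 15, 91424516 to 91426688. ESRP2, an epithelial splicing regulator, had 1 of 162-fold at chromosome 16, 68262450 to 68264218, and POLE3, a DNA polymerase epsilon subunit, 1 of 148-fold at chromosome 9, 116169697 to 116171263. CEBPB, a transcription factor of the stress and inflammatory response, had 1 control peak of 85.8-fold at chromosome 20, 48807120 to 48809227. PDF, the mitochondrial peptide deformylase, and B3GALT6, a galactosyltransferase of proteoglycan synthesis, had peaks of 175-fold and 128-fold. Among these 10 genes, ZNF581 (169-fold) was the case in which the heat list left no number for an unlisted peak; for FURIN, 8 numbers lay between the flanking heat peaks, and for CEBPB 17.

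The heat-only genes with the strongest peaks were BRI3BP, HSPA6, ATXN2L, HIRIP3, DNASE2, GPATCH4, ARC, HMGA1, IL18BP and CTSZ. HSPA6, a strictly inducible member of the Hsp70 family, had 1 heat peak of 49.3-fold over 2652 bases at chromosome 1, 161494036 to 161496687. ARC, an immediate early gene, had 1 of 37.3-fold at chromosome 8, 143693845 to 143695833. ATXN2L, a component of stress granules, had 1 of 27.5-fold at chromosome 16, 28847254 to 28848558. The chromatin proteins HMGA1 and HIRIP3 had peaks of 26.1-fold and 41.4-fold, and the lysosomal enzymes DNASE2 and CTSZ peaks of 107-fold and 36.8-fold. IL18BP (21.3-fold) was the gene of these 10 for which the control list left no number for an unlisted peak; for HSPA6, 13 numbers lay between the flanking control peaks.

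Among the 6030 genes with peaks in both lists, 3277 had equally many peaks, 1508 had more in heat and 1245 had fewer. At least 3 more peaks in the heat list were found for 236 genes, and at least 3 fewer for 59. With 14367 top peaks from each list the numbers were 167 and 80. Above a fold of 36.5 they were 33 and 69, but that filter removes more heat than control peaks and so favours control. The genes named here were chosen after their values were seen. HUWE1, a ubiquitin ligase, had 5 control and 16 heat peaks, EGFR, the epidermal growth factor receptor, 4 and 13, and COL17A1, a hemidesmosomal collagen, 1 and 11. The difference for HUWE1 of 11 peaks fell to 8 with equal numbers of top peaks and to 3 above a fold of 36.5, where EGFR had 1 peak fewer in heat and COL17A1 had no peak left in either list. The largest differences in the other direction were smaller: PPL, the desmosomal plaque protein periplakin, had 10 control and 5 heat peaks, and ADCY3, an adenylate cyclase, 7 and 2. Whether longer regions had been divided into several peaks, for example at exon limits, was not analysed here.

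The heat shock genes held more heat-only than control-only members. Of 38 genes in the list fixed beforehand, 23 had a peak: 12 in both conditions, 3 in control only and 8 in heat only. The heat-only members were HSPA6, HSF1, DNAJC7, AHSA1, HSP90AA1, ST13, HSPH1 and FKBP4, that is an inducible Hsp70, the master transcription factor of the heat shock response, and chaperones and co-chaperones of Hsp70 and Hsp90. HSF1 had 1 heat peak of 39.2-fold at chromosome 8, 145515270 to 145515556, and DNAJC7 had 2, the stronger of 138-fold. HSPH1 (17.7-fold, significance score 59.4) and FKBP4 (12-fold, score 51.5) lay just above the lowest listed score of 50. The control-only members were DNAJA1, with 2 peaks, CACYBP and HSPB8. Heat-only genes made up 72.7% of the 11 single-list members with an exact interval of 39.0 to 94.0%, which includes an even division, and the list stood at the 96.4th percentile of random lists. Above a fold of 36.5 the list had 40% heat-only genes, against 28.8% of all single-list genes (64.5th percentile), and with 14367 top peaks from each list it stood at the 93.1st, whereas the significance filter (99.7th percentile), 7183 top peaks from each list (99.3rd), a listed false discovery rate under 100% (99.4th) and unmatched random lists (97.9th) placed the list outside the central 95% of random lists.

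The other 12 heat shock genes with a peak carried peaks in both conditions. HSPA1A and HSPA1B, near-identical copies whose reads are hard to assign to 1 of them, so that both are uncertain, each had 1 peak with the same boundaries in both lists, at chromosome 6, 31783291 to 31785719 and 31795512 to 31798031. DNAJB1, BAG3, SERPINH1, STIP1, DNAJB4, DNAJB6, HSPA4, HSPA4L, HMOX1 and RGS2 were also listed in both. BAG3, an Hsp70 co-chaperone, had 2 control and 3 heat peaks, HMOX1, the inducible heme oxygenase, 1 and 3, and SERPINH1, the collagen chaperone, 3 and 2. RNA levels in the input libraries were not analysed here, so none of these values separates a change in methylation from a change in RNA amount.

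**Figure D2:**
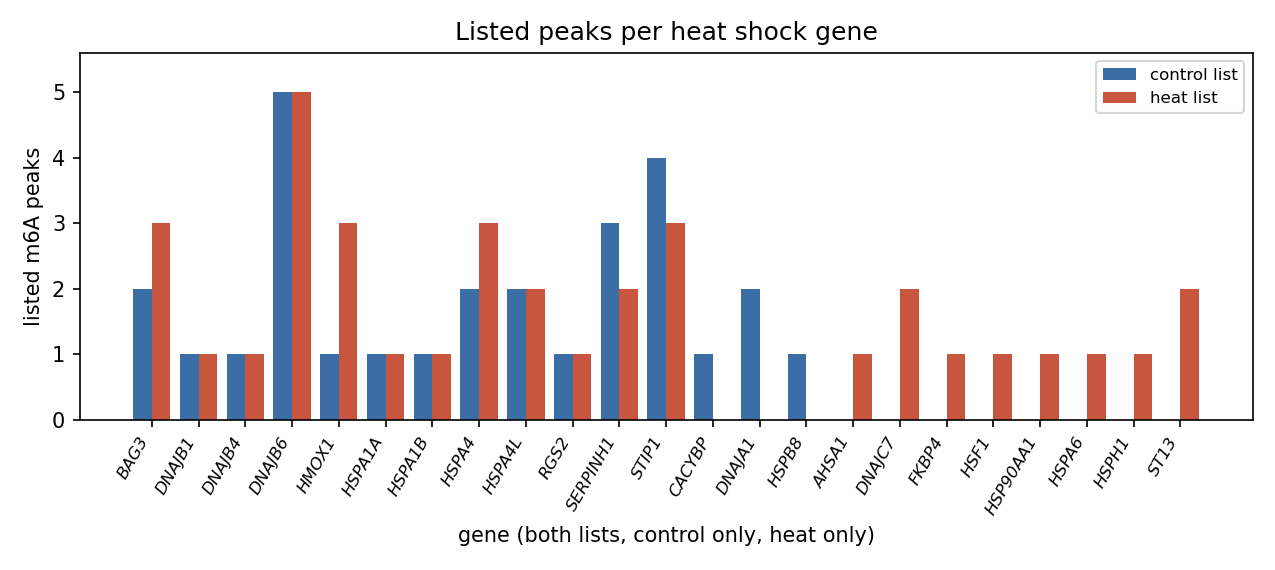
Number of listed m6A peaks (y axis) for each of the 23 heat shock genes with a peak (x axis), in the control list (blue) and the heat list (red), 1 immunoprecipitated library each. There are 12 genes with peaks in both lists, 3 with control peaks only and 8 with heat peaks only.

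Of 22 genes for enzymes and readers of m6A, 17 had a peak, and 15 of these were shared, among them ZC3H13, a component of the methyltransferase complex with 8 peaks in each list, and EIF3A with 8 in each. METTL16, a methyltransferase, was control only (98.5-fold at chromosome 17, 2322452 to 2323890) and HNRNPC, a nuclear RNA-binding protein, heat only (15.4-fold). The list stood at the 51.0th percentile. All 28 chromatin modifiers with a peak, ARID1A and KDM6B included, had peaks in both conditions (46.2nd percentile), and they carried 146 control and 172 heat peaks. Of 32 immediate early genes, 30 had a peak and 28 were shared, JUN and IER3 among them, and DUSP1 and MAFF were control only (26.7th percentile).

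At the authors' threshold the remaining stress and growth lists did not stand apart from random lists. The unfolded protein and integrated stress response list had 17 shared genes, such as PDIA4 and PPP1R15A, with CEBPB in control only and ATF3, ASNS and EIF2AK1 in heat only (82.3rd percentile). ATF3, a stress-induced transcription factor, had 3 heat peaks. In the apoptosis and p53 list 15 genes were shared, BIRC2 and TNFRSF10A among them, CASP9 was control only and 4 genes were heat only, including CASP2, APAF1 and BBC3 (87.7th percentile). In the cell cycle list 13 genes were shared, such as MKI67 and CCND1, 2 were control only, E2F1 among them, and 5 were heat only, including CDKN2A, PLK1 and CDK1 (91.1st percentile). The ubiquitin and proteasome list had 2 control-only genes, CUL3 among them, and 3 heat-only genes, including PSMD12 and USP7 (69.2nd percentile). The list for epithelial-mesenchymal transition and TGF-beta had 17 shared genes, such as SMAD3, 2 in control only, TGFBR1 among them, and FN1, VIM and ITGB1 in heat only (68.1st percentile). With a significance score above 203 the stress response list turned to 20% heat only (24.7th percentile), and the ubiquitin and mesenchymal transition lists to 33.3% (35.4th and 40.4th), beside 37.5% of all single-list genes. These shares rest on few genes: 1 heat only and 4 control only, 2 and 4, and 1 and 2. The cell cycle list then stood at the 98.6th.

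By percentile, 4 of the 14 lists with any peak lay in the outer 5% of random lists, where 0.7 would be expected by chance. For the epithelial list among these the balance, 23.8 percentage points, equalled the upper limit of the central 95%, so it lay on that limit and not past it. The zinc finger genes had the largest imbalance towards control in number: of 291 with a peak, 211 were shared, 67 were control only and 13 were heat only, so that 16.2% of single-list members were heat only (exact interval 8.95 to 26.2%), and none of the 10000 random lists had a balance as low. ZNF581 (169-fold) and ZNF239 (209-fold) were among the control-only members, ZNF395 (101-fold) and ZNF266 (104-fold) among the heat-only members, and ZNF618 and ZNF777 were shared. The 3 lists that leaned towards heat were ribosomal proteins, stress granule and translation factors, and squamous epithelial markers. Of 12 ribosomal protein genes with a peak, 8 were heat only, RPL26, RPL14, RPS6 and RPS26 among them with folds of 14.2, 11.5, 6.40 and 16.6, and 1 was control only (99.9th percentile). For RPS6 the control list left no number for an unlisted peak. The shared ribosomal protein genes included RPL36AL and RPL7L1.

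The stress granule and translation list had 11 shared genes, such as USP10 and EIF4G1, 2 control-only genes, CAPRIN1 among them, and 7 heat-only genes (98.6th percentile). The heat-only genes included ATXN2L, PABPC1, the poly(A)-binding protein, with 1 peak of 10.0-fold at chromosome 8, 101733619 to 101734315, and UBAP2L, a stress granule protein, with 7 heat peaks. Among markers of squamous and cervical epithelium, 12 were shared, such as ELF3 and SFN, 2 were control only and 7 were heat only (98.1st percentile). The heat-only markers included the keratins KRT15 and KRT17, the desmosomal protein JUP with 4 peaks and the hemidesmosomal integrin ITGB4 with 8. Markers of other cell types were scarce: 3 of 18 fibroblast and endothelial genes had a peak, COL1A1 and COL5A1 in both lists and CDH5 in control only (12.8th percentile), and 0 of 18 immune genes had a peak in either list. Above a fold of 36.5 the epithelial list had 16.7% heat-only genes (1 heat only and 5 control only), against 28.8% of all single-list genes, and stood at the 16.5th percentile, and the ribosomal and translation lists fell to the 89.8th and 92.4th. With a significance score above 203 they stood at the 96.8th, 94.1st and 97.0th, so that of these 4 lists the zinc finger genes alone lay outside the central 95% under both filters.

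**Figure D3:**
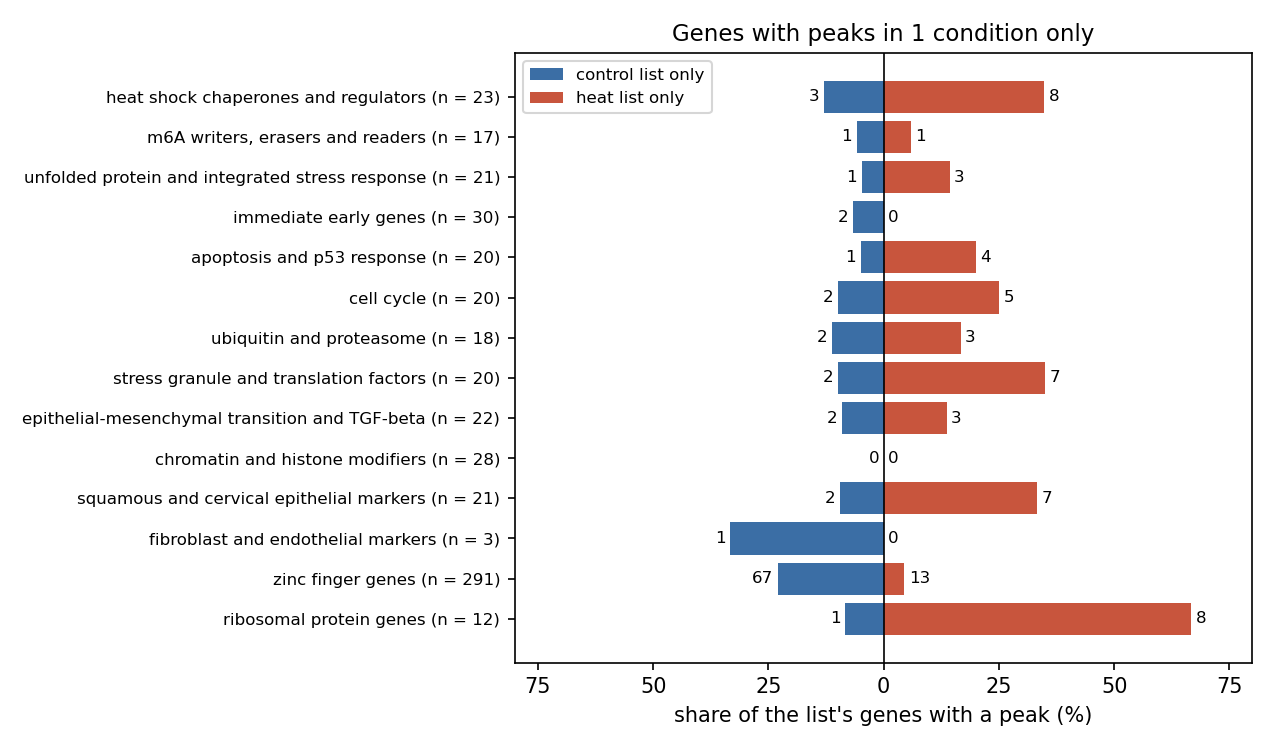
Genes with peaks in the control list only (blue, to the left) and in the heat list only (red, to the right), as a percentage of the genes of each list that had a peak in either condition (n on the y axis); the figures beside the bars are numbers of genes. Zinc finger genes lie mostly to the left (67 against 13), and ribosomal protein genes mostly to the right (1 against 8).

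Single-list genes were not spread evenly over chromosomes, a comparison made after the data were seen, with chromosomes grouped after their counts were known and without the zinc finger genes. On chromosomes 16, 17, 19 and 22, which are known to be rich in genes and in G and C, 286 single-list genes were heat only and 158 control only (64.4% heat only, exact interval 59.8 to 68.9%). On chromosomes 4, 13 and 18, known to be poor in both, 46 of 135 were heat only (34.1%, 26.1 to 42.7%). Chromosome 19 had the highest share, 67.2% (58.5 to 75%), and chromosome 4 the lowest, 31.3% (20.6 to 43.8%), against 50.7% (48.5 to 52.8%) over all chromosomes. The share on chromosome 19 rests on 90 heat-only and 44 control-only genes. The zinc finger genes left out there had 7 heat-only and 40 control-only members, so including them lowers that share. Whether it would still be the highest was not compared.

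**Figure D4:**
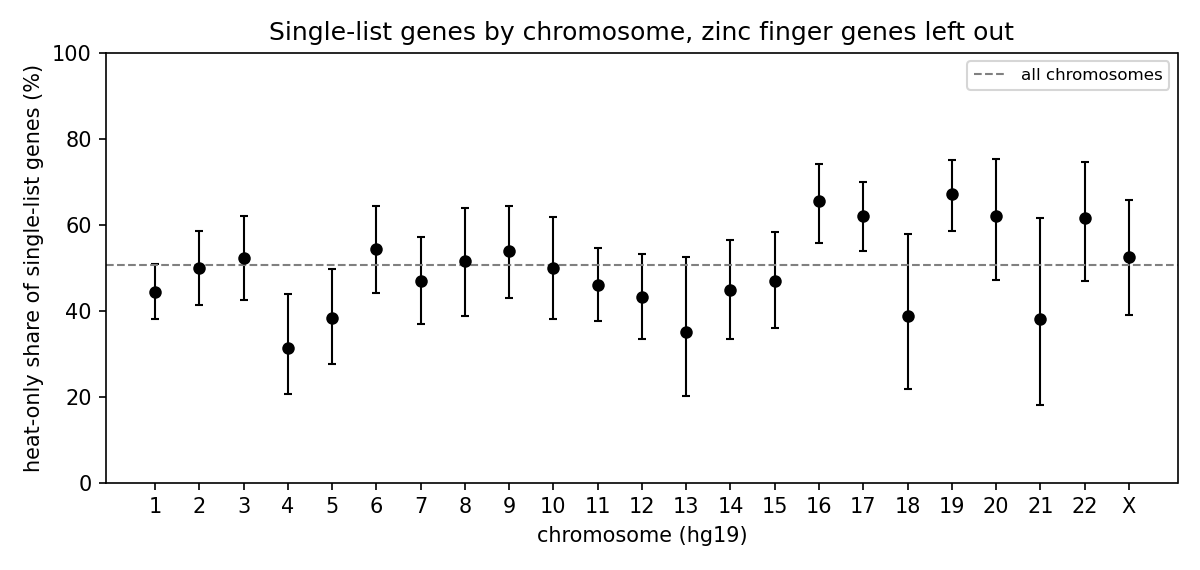
Percentage of single-list genes that had peaks in the heat list only (y axis), by chromosome (x axis), zinc finger genes left out; bars are 95% exact binomial intervals for the counting of genes, and the dashed line is the share over all chromosomes. The share runs from 31.3% on chromosome 4 to 67.2% on chromosome 19.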

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

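The depth per library is unknown and there are no replicates, so these alternatives show only how counts move with thresholds and overlap rules. The filter on the listed false discovery rate, the free peak numbers and overlap under another symbol were chosen after seeing the data. The same holds for all alternatives for the counts of shared genes with at least 3 more or fewer peaks. EGFR, COL17A1, PPL and ADCY3 were also added to the genes followed after their values were seen. Counting every line could change nothing, as the main values already counted each line and no region was listed more than once. Those values are among the 144 given next as the same. Merging regions within 100 bases changed no value beyond its interval. Of the alternative values for the main results 144 counted as the same and 51 moved. Another 8 left the outer 5% of random lists, 5 entered it, and none was labelled reversed. A list's heat-only share counted as the same when inside the exact interval of its main value. The labels therefore do not show that direction held. The stress response share fell from 75% to 20% above a significance of 203. The heat shock share fell from 72.7% to 40% above a fold of 36.5. Each counted as the same. The zinc finger, ribosomal, translation and cell cycle lists kept their direction under every threshold filter. For single genes named by the rule or in the text, 443 values kept their class and 29 did not, and 103 more could not be given because the gene had no peak left, which befell 41 of 115 genes under at least 1 alternative. Peak position along transcripts and the DRACH motif were not run. The fibroblast and endothelial list had no single-list gene left under the fold filter, the discovery rate filter or 7183 top peaks, so it has no share there. No paired analysis was possible because each group has 1 library.

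A fold above 36.5 left 8488 control and 6405 heat peaks, a significance above 203 left 8090 and 7736, and a listed false discovery rate under 100% left 7405 and 7242. The share of control peaks with a heat counterpart was then 47.6%, 67.7% and 68.3%, and of heat peaks with a control counterpart 63.0%, 70.7% and 69.8%. Equal numbers of top peaks gave 69.3% and 69.3%, and at 7183 peaks 69.1% and 69.1%. A 50% reciprocal overlap gave 70.4% and 65.4%, midpoints within 100 bases 63.8% and 59.2%, and stricter peaks against all of the other list 87.5% and 84.0%. With the other single-list peaks left out altogether, so that only the 133 and 181 peaks with no free number stood beside the shared ones, 98.7% and 98.3% of the peaks that remained were shared. These high shares follow from leaving out most single-list peaks.

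Genes in both lists numbered 3428 with the fold filter, 3925 with the significance filter, 3631 with 7183 top peaks and 3695 with the discovery rate filter, against 6030. Control-only genes numbered 1974 with the fold filter against 1108, and heat-only genes 797 against 1082. The heat-only share of all single-list genes was 28.8% with the fold filter, 37.5% with the significance filter, 43.1% with 14367 top peaks, 41.3% with 7183 and 39.5% with the discovery rate filter, against 49.4%. Stricter peaks against all of the other list left 370 and 321. Shared genes with at least 3 more heat peaks and at least 3 fewer numbered 33 and 69 with the fold filter, 66 and 20 with the significance filter, 70 and 14 with 7183 top peaks and 67 and 17 with the discovery rate filter, against 236 and 59.

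Among the gene lists, the zinc finger genes had 11.5 to 18.3% heat only under the threshold filters. The heat shock list moved from the 96.4th percentile to the 99.7th with the significance filter, the 99.3rd with 7183 top peaks, the 99.4th with the discovery rate filter and the 97.9th without matching, but to the 93.1st with 14367 top peaks and the 64.5th with the fold filter. The cell cycle list reached the 98.6th with the significance filter. The ribosomal list fell to the 89.8th with the fold filter, the 94.1st with the significance filter, the 92.2nd with 7183 top peaks and the 93.4th with the discovery rate filter. The translation list fell to the 92.4th with the fold filter and the 97.0th with the significance filter, and the epithelial list to the 16.5th (16.7% heat only) and the 96.8th. The heat-only share of the m6A list went from 50% to 0% with the fold, significance and discovery rate filters and with 7183 top peaks. It rested on 1 heat-only and 1 control-only gene at the authors' threshold. With the fold filter there were 0 and 4, and with each of the other 3 settings 0 and 1. With the fold filter, which lowered the share of all genes too, the apoptosis list had 25% (1 heat-only and 3 control-only genes, 56.5th percentile). The mesenchymal transition list then had 12.5% (1 and 7, 9.37th), and 0% (0 and 2, 17.5th) with the discovery rate filter. These percentiles lay inside the central 95%, as did those of the m6A list. The cause was not tested.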

Other observations

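Beyond the lists fixed in advance, gene ontology terms given in the files were compared by heat-only minus control-only genes, scaled by the spread over permutations. Of 523 terms with 20 to 300 genes, 32 leaned to heat only beyond a 2-sided 1% normal limit. When the genes' classes were permuted 2000 times within bins of peak number, the median was 2 and the highest 2.5% of permutations began at 7. Towards control only there were 2, against a median of 2. The terms furthest towards heat only were viral process (48 heat-only and 17 control-only genes), basement membrane (10 and 0), mitotic spindle (9 and 0), selenium compound metabolic process (13 and 2) and focal adhesion (39 and 15), and translation had 33 and 13. The 2 terms towards control only were the Cul3-RING ubiquitin ligase complex (0 heat-only and 8 control-only genes) and methylation (3 and 14). Other terms towards heat only included translational initiation (15 heat-only and 4 control-only genes) and translational elongation (11 and 2). Overlap with the ribosomal and translation lists was not removed, so the terms are not evidence apart from those lists. The terms share genes and are not independent, and genes are not replicates.

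The ontology comparison, the test on chromosomes 4, 13 and 18 and the permutations that pick lists again were chosen after the result was seen, as were the 3 lists joined here, the grouping of chromosomes, and the use of the interval of a median, in place of the median itself, to decide the tests of fold. The first pattern is that ribosomal, translation and squamous epithelial genes, many of which are known to be abundantly expressed, leaned to heat only; the lists were joined because they leaned that way, so the size of the lean is overstated. With 14367 top peaks from each list, 19 of 24 single-list members were still heat only (79.2%, exact interval 57.8 to 92.9%), so the lean remained at equal list lengths. The interval does not allow for the choice of lists, so it does not decide whether the longer heat list contributed. That 22 of 48 members with a heat peak lacked a control peak (45.8%) does not bear on weak calls, because the lists were picked for it. Classes were then permuted within deciles of significance and quintiles of fold, and the 3 highest lists picked again each time. None of 1000 permutations reached the excess seen (6.19 SD, against a median of 2.13), the outcome set against weak calls alone. Quintiles of fold are a coarse match for members with folds as low as those given next, so weak calls are not excluded. The 22 heat-only members had heat peaks of low fold, at the 10.9th percentile of heat peaks of the same decile of significance (95% interval of the median 1.74 to 19), against 49.6 for all heat-only genes. This was the outcome predicted for abundant RNA passing the threshold at a low fold. Shared members of these lists were not compared, so the low folds do not tell why the genes were heat only. More m6A on these transcripts, or more of the RNA, after heat stays open and was not tested, since RNA levels were not analysed here.

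The second pattern is the lean of zinc finger genes to control only. Of 278 zinc finger genes with a control peak, 67 lacked a heat peak (24.1%). Sets matched on the significance and fold of the best control peak had 11.9 to 19.4%, with a median of 15.5%. The excess over these matched sets argues against weak calls as its cause. Outside chromosome 19, where many of these genes are clustered, 6 of 33 single-list members were heat only (18.2%, exact interval 6.98 to 35.5%), which argues against those clusters as the cause. Too few reads on rare RNAs in the heat library cannot be told apart from a biological loss: control-only members lay at the 59.7th percentile of fold for their significance (45 to 69.4), between the limits set for either outcome, and all control-only genes at the 63.8th. Less of these RNAs after heat, or less m6A on them, stays open as untested.

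The third pattern is the division by chromosome, again without the zinc finger genes. With equal numbers of top peaks, 257 of 435 single-list genes on chromosomes 16, 17, 19 and 22 were heat only (59.1%, exact interval 54.3 to 63.7%), so the lean remained at equal list lengths. These chromosomes were grouped after their shares were seen, and the interval does not allow for that. Whether the longer heat list contributed is therefore not decided. Abundant RNA at low fold was not settled: the heat-only genes there lay at the 44.6th percentile of fold for their significance, above the bound of 40 set for ruling it out, but with an interval of the median (38.7 to 53.4) that reaches below it; judged by the median alone, as first set, it would have been ruled out. A difference in base composition between the libraries is a candidate explanation, with the opposite share on chromosomes 4, 13 and 18 (34.1%), but these chromosomes were picked for it, and it cannot be told apart from an effect of heat on gene-rich regions because the sequence of the peaks was not used here.

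Of the peaks at the ceiling of the significance score, 26 of 1466 in the control list (1.77%, 95% Wilson interval 1.21 to 2.59%) and 21 of 752 in the heat list (2.79%, 1.83 to 4.23%) had no counterpart, and for 6 and 4 of these no number was left for an unlisted peak. Shared boundaries were common, since 6780 regions, 65.8% of the shared control peaks, began and ended at the same base in both lists. Whether these boundaries follow exon limits was not checked, because no transcript models were used here.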
